A study of Mus musculus with 2 samples.

How the data were processed

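RNA of mouse leukemia stem cells, described as polyadenylated, was sequenced with paired ends in 2 libraries. They are numbered in the labels as biological replicates 1 and 2 of a single experiment. The labels give different biosamples and the same donor record for the libraries, and nothing further on how the cells were split, so the spread between them may be partly technical. Each library had a gene table and a transcript table made by the authors on mm10 with GENCODE M4 gene models, per the file headers and the accompanying readme. The aligner and the quantifying program are not given in the sources used here; the column names are those of RSEM.

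The authors gave expected counts, which are estimated numbers of fragments that need not be whole, for each gene and transcript. The deposited TPM values are relative to every row of a table, and the deposited FPKM values and the authors' posterior mean TPM values were used as alternatives. The share of each transcript in its gene is the deposited percent. The authors' posterior SD of the count and their interval bounds, per the file headers, carry the scale of the signal they belong to and were not used for any comparison. A gene table had 69691 rows, of which 43346 carried an Ensembl identifier, and 42462 of these matched a gene of the GENCODE M21 annotation of the same assembly by identifier without version. M21 gave symbols, gene types, positions, transcript length and GC content, taken from the transcript sequences. Rows of numbered small features and spike-ins were left out of the comparisons.

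Of the 26 gene lists fixed before the data were examined, 365 of 366 genes were analysed. The lists covered sort markers, stem and early progenitor, erythroid, megakaryocyte, granulocyte-monocyte progenitor, mature neutrophil, macrophage, mast cell and basophil, B lineage, T and NK, dendritic, fibroblast and stromal, endothelial and other-tissue genes, and cell cycle, p53, Friend virus, BMP and hedgehog, Notch and Wnt, interferon, antigen presentation, hypoxia, immediate early, epigenetic and sex-linked genes. Another 3 lists, of ribosomal protein, mitochondrial and replication-dependent histone genes, were defined by symbol. Named genes were fixed by rule: the sort markers, Mst1r, Spi1, Fli1, Trp53, Epor and the sex-linked genes always; up to 4 most abundant members per list, and defining lineage genes under 0.1 TPM; the 10 most abundant nuclear protein-coding genes outside the ribosomal proteins; in each direction the 10 genes with the largest replicate ratio at a mean of 5 TPM or more; and isoform genes with a mean of 1 TPM or more. Other genes named (Hbb-y, Hbb-bh1, Slc4a1, Dcn, Hbb-bt, Jun, Fos, Hlf, Meis1, Procr, Slamf1 and those of the closing observations) were chosen after their values had been seen. The remaining list gene and some genes that the rule names are not reported here.

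A gene was counted as detected at 1 TPM or more. List levels are medians of the mean log2(TPM + 1), placed among 10000 random lists of the same size from protein-coding genes. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, which gave TMM scaling and a common dispersion from an intercept-only design; DESeq2 1.42.0 gave alternative size factors. The ratio of the libraries used a prior count of 0.5 and an exact binomial 95% interval, and list ratios were placed among random lists matched on mean expression in 20 bins. A list was described as higher or lower below the 2.5 or above the 97.5 percentile, limits set after the values had been seen. Under an alternative, a coefficient of variation was counted as moved beyond 5% and a correlation beyond 0.02, likewise set late. No p-value was computed, since there was 1 group. The criterion for genes apart was tested on simulated data before use: with counting error alone it recovered 100% of 200 changed genes and called 1 unchanged gene of 11729, and with a coefficient of variation of 0.3 it recovered 98.0% and called 575 of 11705. The floor for a count of 0 was 3 counts.

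Genes were matched to annotated pseudogenes by 30 or more shared words of 25 bases. Alternatives were other TPM minimums, FPKM, posterior mean TPM, TPM over nuclear protein-coding genes, pseudocounts, count filters, scalings, prior counts, length-matched lists and each library alone. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures in matplotlib 3.10.9.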

Results

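Gene expression was measured by paired-end sequencing of RNA, described as polyadenylated, in mouse leukemia stem cells. Per the labels these cells were infected with Friend virus, a retrovirus that causes erythroleukemia in mice, and were positive for CD34, CD133 (the product of Prom1), Kit and Sca1 (the product of Ly6a). They came from pooled male and female adults of 10 to 12 weeks of a strain with the sensitive allele of Fv2, the locus of Mst1r. The series held 1 group with 2 biological replicates, so levels are given with the spread between the replicates and nothing was compared between conditions. The files summed to 23575315 expected counts in replicate 1 and 22541765 in replicate 2. Of 21474 protein-coding genes, 8942 had a level of at least 1 TPM, the deposited length-normalised share of transcripts, in both libraries, and 6278 had 0 counts in both. Values are means ± SD of the deposited TPM (n = 2) unless stated otherwise, and the gene positions are on mm10.

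The first question was whether the RNA carried the markers named in the labels. Transcripts of the 4 sort markers were scarce in both libraries. Ly6a (ENSMUSG00000075602.6, chromosome 15, 74994877 to 74998031) had 1.80 ± 0.495 TPM and Kit (ENSMUSG00000005672.8, chromosome 5, 75574916 to 75656722), the stem cell factor receptor, 1.44 ± 0.530 TPM. Cd34 (ENSMUSG00000016494.5, chromosome 1, 194938819 to 194961279) had 1.03 ± 1.08 TPM, from 83 counts in replicate 1 and 13 in replicate 2. Prom1 (ENSMUSG00000029086.11, chromosome 5, 43993620 to 44102032) had 3 counts in replicate 1 and 0 in replicate 2, where 0 counts allow up to 0.05 TPM. The median of the 4 markers lay at the 50.02 percentile of random lists of 4 protein-coding genes, and 2 of the 4 reached 1 TPM in both libraries.

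Other stem and early progenitor genes were mixed, some of them abundant and others scarce. Of the 24 genes of that list, 16 reached 1 TPM in both libraries and 9 had a mean of 100 TPM or more. Lmo2 had 721 ± 489 TPM, Gata2 514 ± 61.1 TPM, Tal1 470.0 ± 25.4 TPM and Ikzf1 432 ± 23.7 TPM, all of them transcriptional regulators of blood progenitors. Runx1 had 114 ± 31.5 TPM and Myb 17.8 ± 8.08 TPM. In contrast, Mecom, a regulator of long-term stem cells, had 0.0300 ± 0.0424 TPM, and Erg had 1.05 ± 0.516 TPM. The list median lay at the 98.9 percentile of random lists, and the median member had 8.85 TPM. This percentile describes the mixed list as a whole and not the scarce genes in it.

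The erythroid list was the most abundant of the lineage lists. All 23 analysed members reached 1 TPM in both libraries, 12 had a mean of 100 TPM or more, and the list median was at the top of the random lists, at the 100 percentile. The adult alpha globins Hba-a1 (92215 ± 58206 TPM) and Hba-a2 (46365 ± 33681 TPM) and the beta globin Hbb-bs (26664 ± 11388 TPM) led the list, and globin genes together took 11.0% of all TPM in replicate 1 and 22.2% in replicate 2. The 2 alpha globin genes are near-identical copies, so the split between them is uncertain. The embryonic globins Hbb-y and Hbb-bh1 had 0 counts in both libraries; these 2 genes were chosen after their values had been seen. Klf1 (chromosome 8, 84901928 to 84905291), the erythroid Krüppel-like factor, had 1329 ± 390.3 TPM, Epor (chromosome 9, 21958897 to 21963506), the erythropoietin receptor, 472 ± 259.9 TPM, and Gata1 192 ± 165 TPM. Slc4a1, the red cell anion exchanger, had 928 ± 694 TPM.

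**Figure D1:**
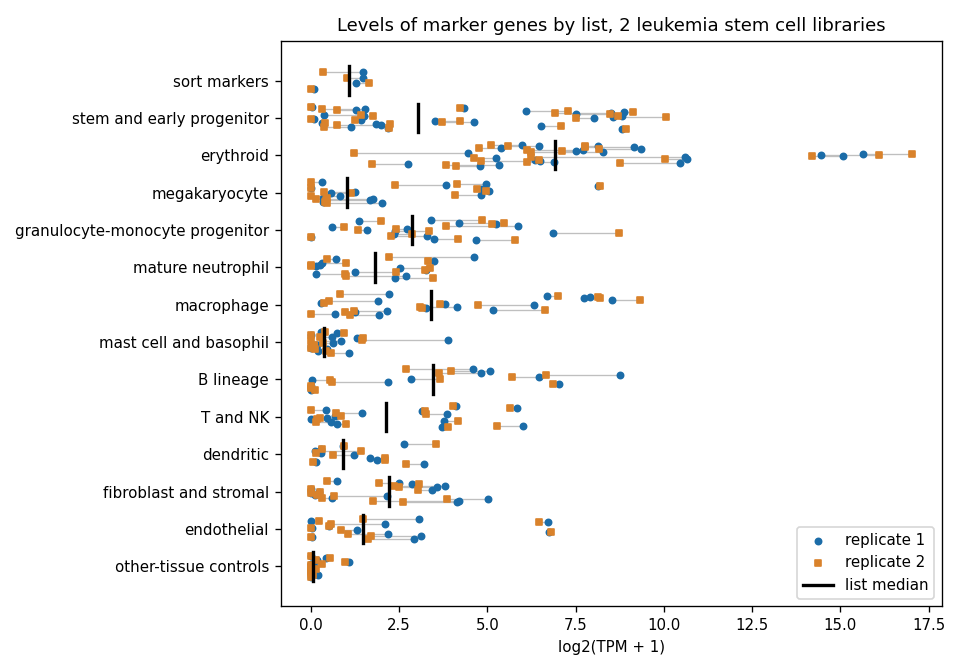
Level of each gene of the 14 marker lists as log2(TPM + 1), with replicate 1 as circles and replicate 2 as squares joined by a line, and the list median over the mean of both libraries as a black bar. The erythroid median, 6.92, lies above all other lists shown, and the sort marker median is 1.09.

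Genes of other blood lineages were present at lower levels. In the macrophage list, 11 of 16 genes reached 1 TPM in both libraries, led by the complement genes C1qc (503 ± 191 TPM), C1qa (259 ± 30.8 TPM) and C1qb (253 ± 57.0 TPM), while the receptor Axl had 115 ± 17.7 TPM and the list median lay at the 99.0 percentile. In the B lineage list, 7 of 12 genes did so, with Cd79a at 268 ± 238 TPM, Pax5 at 123 ± 11.8 TPM and Cd79b at 69.5 ± 26.0 TPM, and a median at the 98.1 percentile. In the granulocyte-monocyte progenitor list, 13 of 15 genes did so, with Irf8 at 271 ± 221 TPM, Spi1 at 39.1 ± 20.6 TPM, Csf2rb at 35.4 ± 2.02 TPM and Csf3r at 35.4 ± 31.2 TPM, and its median lay at the 95.5 percentile, or the 79.6 percentile among lists matched on GC content. Of 16 megakaryocyte genes, 6 did so (63.8 percentile). Gp5, a platelet glycoprotein, had 288 ± 7.47 TPM, Itga2b 31.2 ± 1.24 TPM, Gp9 26.3 ± 1.62 TPM and Gp1ba 23.4 ± 9.33 TPM. In replicate 1 alone, 10 megakaryocyte genes reached 1 TPM.

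The remaining marker lists ranged from the 12.6 to the 88.4 percentile of random lists. Of the T and NK genes, 7 of 14 reached 1 TPM in both libraries (88.1 percentile), with Cd2 at 52.9 ± 4.87 TPM, Tcf7 at 50.6 ± 18.4 TPM, Bcl11b at 15.8 ± 0.693 TPM and Lck at 14.9 ± 3.01 TPM. Of the mature neutrophil genes, 7 of 12 did so (81.1 percentile), with Camp at 13.8 ± 14.3 TPM, Lcn2 at 9.63 ± 0.933 TPM, Ngp at 8.50 ± 0.191 TPM and S100a9 at 7.14 ± 4.07 TPM. Of the fibroblast and stromal genes, 8 of 15 did so (88.4 percentile), with Sparc at 22.4 ± 12.7 TPM and Thy1 at 11.0 ± 8.22 TPM, and Dcn, which encodes decorin, had 0 counts. The endothelial list had 6 of 12 (74.4 percentile), with Plvap at 109 ± 2.79 TPM and Eng at 96.1 ± 13.1 TPM, but Cdh5 at 4.61 ± 3.95 TPM. The dendritic list had 4 of 10 (56.4 percentile), with Batf3 at 8.00 ± 3.88 TPM. The mast cell and basophil list had 2 of 14 (37.0 percentile), with Il1rl1 at 7.75 ± 8.47 TPM. None of the 12 genes of other tissues reached 1 TPM in both libraries (12.6 percentile), and Alb and Ttr, which encode albumin and transthyretin, had 0 counts in both.

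Genes of Friend virus disease were examined because the labels name the virus and its sensitive host allele. Of the 12 genes for virus entry and signalling, 11 reached 1 TPM in both libraries, at the 99.9 percentile. Besides Epor, the kinase Lyn had 112 ± 1.82 TPM, the adaptor Grb2 47.7 ± 13.0 TPM and Slc7a1, the receptor of ecotropic murine retroviruses, 37.9 ± 24.5 TPM. Mst1r (ENSMUSG00000032584.8, chromosome 9, 107906873 to 107920383) had 16.5 ± 7.83 TPM. Its full-length coding transcript, Mst1r-201, held 10.5% of the gene's TPM in replicate 1 and 22.3% in replicate 2. The largest share of TPM over both was that of the retained-intron transcript Mst1r-202 (positions 107916224 to 107916904), with 45.0% ± 11.4. Mst1r-204, annotated as a target of nonsense-mediated decay, led in replicate 2 with 40.7%. Mst1r-202 is only 600 bases long, which raises its TPM, and had few expected counts, 108 in replicate 1 and 36.9 in replicate 2. The long transcripts had more, with 446 and 405 for Mst1r-204 and 210 and 223 for Mst1r-201. These shares are among the 4 annotated Mst1r transcripts only. Reads from a form that is not annotated could not be told apart from them. Of the 7 genes at or near loci altered in Friend leukemias, 6 reached 1 TPM in both libraries, at the 99.6 percentile. Myc had 434 ± 81.7 TPM, Trp53 (chromosome 11, 69580359 to 69591873) 119.8 ± 7.53 TPM, Nfe2 83.5 ± 4.29 TPM, and the ETS factors Spi1 (chromosome 2, 91082390 to 91115756) 39.1 ± 20.6 TPM and Fli1 (chromosome 9, 32422204 to 32542861) 5.65 ± 0.742 TPM.

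Among 21 genes examined for isoforms with a mean of 1 TPM or more, 19 had more than 1 transcript in the tables. Of these, 12 had the same leading transcript in both libraries, and in 7 it held over 90% in both, or in 6 by the posterior mean shares, where Kit-201 held 42.0% and 39.7% of Kit in place of 94.6% and 100%. Gata1-201 held 99.6% ± 0.509 of Gata1 and Runx1-203 95.9% ± 2.01 of Runx1. In Lmo2, the short transcript Lmo2-206 held 30.7% in replicate 1 and 88.0% in replicate 2, and Lmo2-207 44.0% and 5.81%. In Ikzf1, Ikzf1-202 held 21.7% and 65.7%. In Trp53, Trp53-203 held 44.0% and 0.02%, but 26.7% and 9.25% by the posterior mean shares, and Trp53-201 3.64% and 25.2%, but 21.5% and 16.0%, in the opposite direction. Trp53-204, annotated as a processed transcript, held 11.9% and 43.2%, and 12.0% and 43.2% by the posterior mean shares. All of these shares are the authors' estimates from reads that the transcripts largely have in common.

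Cell cycle genes, p53 targets, leukemia regulators and immediate early genes were abundant. Of the 23 cell cycle genes, 22 reached 1 TPM in both libraries (100 percentile), with Mcm2 at 295 ± 64.9 TPM, Ccna2 at 286 ± 39.3 TPM, Aurkb at 255 ± 27.7 TPM and Cdc20 at 231 ± 89.3 TPM. Of 16 CDK inhibitors and p53 targets, 13 did so (100 percentile), and Bbc3, which encodes the death-promoting protein PUMA, led with 375 ± 255 TPM, followed by Ccng1 at 158 ± 84.9 TPM and Bax at 115 ± 57.8 TPM. Of 21 leukemia and epigenetic regulators, 16 did so (99.9 percentile). Mcl1 and Bcl2l1, which encode inhibitors of cell death, had 422 ± 204 TPM and 128 ± 49.3 TPM, and Dnmt1, the maintenance DNA methyltransferase, 91.0 ± 24.8 TPM. Of 14 immediate early and heat shock genes, 12 did so (99.9 percentile), with Jund at 523 ± 293 TPM, Junb at 305 ± 105 TPM, Zfp36 at 197 ± 47.5 TPM and Egr1 at 164 ± 17.3 TPM.

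Signalling and metabolic lists ranged more widely. All 10 antigen presentation genes reached 1 TPM in both libraries (99.99 percentile), led by Cd74 (912 ± 649 TPM) and H2-Ab1 (409 ± 401 TPM), with H2-D1 at 181 ± 66.0 TPM and H2-K1 at 169 ± 124 TPM. Of 12 Notch and Wnt genes, 10 did so (99.2 percentile), with Dtx1 at 61.5 ± 18.0 TPM, Ctnnb1 at 33.6 ± 10.5 TPM, Hes1 at 30.1 ± 7.67 TPM and Nrarp at 28.7 ± 6.74 TPM. Of 16 hypoxia and glycolysis genes, 12 did so (97.3 percentile), with Aldoa at 985 ± 428 TPM, Ldha at 314 ± 99.7 TPM, Eno1 at 285 ± 346 TPM and Pkm at 83.4 ± 28.9 TPM. Of 20 interferon genes, 10 did so (85.8 percentile), with Irf7 at 297 ± 159 TPM, Bst2 at 111 ± 42.3 TPM and Irf9 at 108 ± 123 TPM. Of 18 BMP and hedgehog genes, 11 did so (84.2 percentile), with Smo at 28.8 ± 0.516 TPM, Id3 at 16.1 ± 1.22 TPM, Gdf15 at 12.4 ± 5.81 TPM and Smad4 at 12.4 ± 2.10 TPM.

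A small number of genes took much of the RNA. The 10 highest genes held 26.8% of TPM in replicate 1 and 35.2% in replicate 2, and the 100 highest held 48.7% and 55.7%. Besides globins, the highest nuclear protein-coding genes outside the ribosomal proteins were the histone genes Hist1h2ao (26741 ± 5405 TPM) and Hist1h2ap (12951 ± 10094 TPM), the ferritin genes Fth1 (11718 ± 120.4 TPM) and Ftl1 (7024 ± 2311 TPM), Ptma (9516 ± 6626 TPM), Ddx5 (6068 ± 311 TPM) and Ran (5362 ± 725 TPM). Of 67 replication-dependent histone genes, 55 reached 1 TPM in both libraries, with 5.43% of TPM in replicate 1 and 3.16% in replicate 2. These genes are near-identical copies and their single values are uncertain. How their share relates to the selection of polyadenylated RNA was not tested. Of 84 ribosomal protein genes, 81 did so, with 10.7% of TPM in replicate 1 and 7.28% in replicate 2. Of 13 mitochondrially encoded mRNAs, 10 did so, with 3.89% and 0.786% of TPM, and several share reads with nuclear copies.

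Sex-linked genes were examined because the cells were pooled from males and females. Xist, the X inactivation RNA of female cells, had 72.8 ± 66.9 TPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in both libraries. For Eif2s3y, 0 counts allow up to 0.13 TPM in each library, and this limit covers counting error only.

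The replicates differed widely in the levels of individual genes, and the next comparison describes these 2 libraries and not conditions. Across 10399 protein-coding genes, log2(TPM + 1) had a Pearson correlation of 0.907 and a Spearman correlation of 0.891; genes are not independent replicates. The biological coefficient of variation from edgeR was 0.561. Of 11708 genes with 20 or more counts, 1028 were more than 2-fold higher in replicate 2 and 1711 in replicate 1 with the exact 95% interval of the ratio wholly outside 2-fold. Thus 37.5% of the genes apart were higher in replicate 2, but 13.8% with TPM ratios and 12.0% with total-count scaling, which moved the median log2 ratio of all genes from −0.04 to −0.47. In simulated libraries with this coefficient of variation for every gene, 3145 genes with no difference in mean passed the same criterion. The coefficient was estimated from these 2 libraries as 1 group, so any real difference between them was already counted as spread. The simulation therefore cannot decide whether a gene that passes stands apart from the general spread, and passing was not taken as evidence that it does. Estimated with a trend on abundance, the median coefficient ran from 0.74 in the least abundant genes to 0.44 in the most abundant.

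Gene groups differed together between the libraries. Relative to 10000 random lists matched on expression, erythroid genes were lower in replicate 2 (median log2 ratio −0.51, 0.025 percentile), with 7 of 23 higher in replicate 1, among them Hbb-bt (−3.90), and 2 higher in replicate 2, Hba-a1 (1.85) and Hba-a2 (2.08). B lineage genes were lower in replicate 2 (−1.10, 0.58 percentile), although Pax5 was at 0.14 and immunoglobulin gene segments, which are outside the list, took 0.177% of counts in replicate 1 and 0.338% in replicate 2. Also lower in replicate 2 were endothelial genes (−1.13, 1.69 percentile), cell cycle genes (−0.65, 0.03 percentile), ribosomal protein genes (−0.60) and mitochondrial mRNAs (−2.22), the last 2 below every random list. Of their members, 2 of 9 endothelial, 8 of 23 cell cycle, 29 of 82 ribosomal protein and 7 of 11 mitochondrial genes were higher in replicate 1. Higher in replicate 2 were 1 cell cycle gene, Cdc20 (1.30), and 7 ribosomal protein genes. Granulocyte-monocyte progenitor genes were higher in replicate 2 (1.09, 99.95 percentile), with 5 of 14 higher there, among them Spi1 (1.63). The other way, 1 member was higher in replicate 1, Csf3r (−1.48). Immediate early and heat shock genes were also higher in replicate 2 (1.31, 100 percentile), with Jun at 2.17 and Fos at 2.06. Total-count scaling and TPM ratios lowered the median log2 ratio of all genes to −0.47 and −0.45; the granulocyte-monocyte progenitor median was then 0.66 and 0.76, and the immediate early and heat shock median 0.89 and 0.93. With TPM ratios the B lineage median was −1.21 and lay among the random lists. Dendritic genes were higher in replicate 2 (0.79, 97.54 percentile), but lay among the random lists with TPM ratios (0.20), a prior count of 5 (0.77) or matching on GC content. Histone genes had a median of 0.37 (99.88 percentile), but lay at the 48.2 percentile among lists also matched on GC content; with TPM ratios it was −0.11, above the −0.45 of all genes. Sort markers (−0.20, 55.3 percentile), stem and early progenitor genes (0.47, 92.0 percentile) and macrophage genes (0.36, 85.1 percentile) lay among the random lists, but stem and early progenitor genes were at the 97.55 percentile among lists also matched on GC content.

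Among genes apart with a mean of 5 TPM or more, those with the largest ratios toward replicate 2 included H2-Ab1 (log2 ratio 2.95, 95% interval 2.89 to 3.01), Lst1 (4.77, 3.72 to 6.36), Zbed5 (4.33, 3.87 to 4.87) and Fkbp2 (3.03, 2.95 to 3.12). Pet117 and Gm16867 had 0 TPM in replicate 1 and 11.3 and 12.4 TPM in replicate 2. Toward replicate 1 they included Mrpl32 (−5.23, −5.77 to −4.78), Lsm8 (−5.83, −7.59 to −4.73) and Rnaset2b (−7.29, −8.50 to −6.44). Rsc1a1, Pagr1b and Gm20671 had 0 TPM in replicate 2 and 12.0, 15.5 and 22.2 TPM in replicate 1. The intervals cover counting error only. They do not cover how reads shared between similar or overlapping genes were assigned, which was not examined for these genes.

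The ratio between the libraries varied with the base composition of the transcripts. With genes split into 10 equal groups by GC content, the median log2 ratio of replicate 2 over replicate 1 was −0.73 in the lowest group and 0.69 in the highest. The Spearman correlation across genes was 0.313 with GC content and −0.0571 with transcript length.

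**Figure D2:**
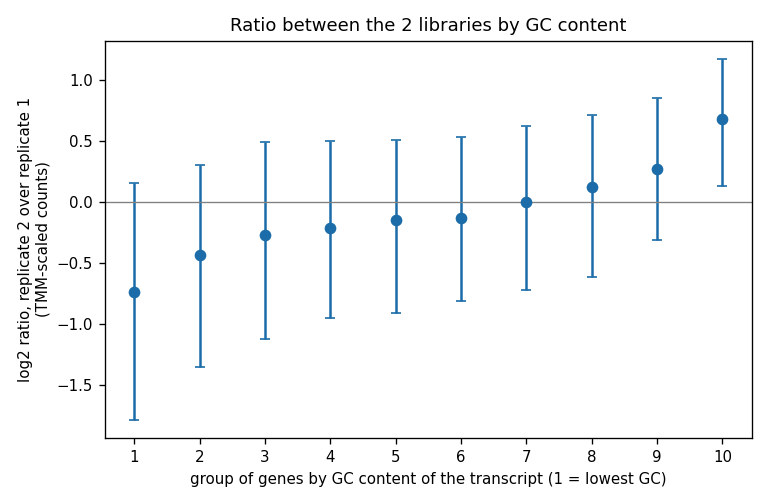
Median log2 ratio of replicate 2 over replicate 1 in TMM-scaled counts for 10 equal groups of genes ordered by GC content of the transcript, with bars from the lower to the upper quartile of the genes. The median runs from −0.73 in the lowest group to 0.69 in the highest.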

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

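Of the tests in this part, only that on pseudogene copies was written before its result was seen; those on GC content, transcript length, sort marker GC content, cells outside the gate and both Y-linked explanations were chosen after.

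Rows outside the protein-coding genes carried counts above the limit of 3 counts that a count of 0 allows. Rows annotated as long intergenic RNAs took 14.3% of counts in replicate 2 and 6.19% in replicate 1. Most were on Gm26917, with 2850446 counts in replicate 2 and 1170803 in replicate 1. The classes are those of the annotation, and the origin of these reads, ribosomal RNA included, was not tested. Pseudogenes took up to 1.62%, immunoglobulin gene segments 0.338% (replicate 2, against 0.177% in replicate 1), rows without a gene in the reference annotation 0.229%, other long noncoding RNAs 0.193%, small and ribosomal RNAs 0.0628% and T cell receptor segments 0.00375%. The numbered small features took 1.7e-05%, from 4 counts in replicate 1.

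The genes apart between the libraries numbered 2739. Removing the trend of the ratio on GC content left 2481, and removing that on transcript length left 2686, so neither trend accounts for the whole pattern. Of the genes apart, 74.3% had no annotated pseudogene copy, against 79.2% of all genes compared, a share that left the test little room to come out otherwise. Among genes with no copy 21.9% were apart, against 23.4% of all genes compared. Reads shared with annotated pseudogenes thus do not account for most of the pattern, and reads shared with other genes were not examined. Part of the pattern may still follow GC content and pseudogene copies. The median log2 ratio of replicate 2 over replicate 1 was 0.01 in genes with 0 pseudogene copies, −0.19 with 1 to 4, −0.58 with 5 or more but under 20 and −0.73 with 20 or more, and −0.45 and −0.49 in the last 2 groups with the GC trend removed. Of the 10 lists described as higher or lower, 8 stood apart among GC-matched lists too, and dendritic and histone genes did not. No biological explanation was tested, since the design has 1 group.

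The 4 sort markers had low transcript levels, at most 1.80 TPM on average. Of 20 stem and erythroid genes at or under 48.5% GC, the highest of the markers, 14 exceeded the highest marker. Transcripts of such GC content were thus not lost altogether. A partial loss cannot be decided on, since abundant genes would exceed 1.80 TPM even after a large one, and the erythroid median was 139 TPM. RNA from cells outside the sorted gate remains open: the median over all members was 11.7 TPM in the B lineage list and 10.2 TPM in the macrophage list, above the highest marker but under the 10 times that the test asked for. Immunoglobulin gene segments, outside the B lineage list and so outside this test, took 0.220% of TPM in replicate 1 and 0.438% in replicate 2. Members of the 2 lists varied widely. Of 12 B lineage genes, 6 had a mean of 10 TPM or more and 3 were under 0.1 TPM. Of 16 macrophage genes, 8 had 10 TPM or more, while Adgre1 had 2.23 ± 2.04 TPM. A sort for all 4 markers should remove such cells, some of these genes are also transcribed in progenitors, and the values do not show how many such cells there were. No biological explanation, such as low transcript with lasting surface protein, was tested.

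The Y-linked genes had no reads although the labels give pooled sexes. Whether the Y chromosome was missing from the reference used cannot be told apart from an absence of male cells: the share with a count was 0% among only 2 Y-linked pseudogenes that resemble an abundant gene, against 34.7% of 1060 on other chromosomes, too few to decide. The highest count of the 4 Y-linked genes in a library was 0. Of 1569 rows on chromosome Y, 1 had counts, Gm37158 with 1 in replicate 1 and 11 in replicate 2. The gene models used thus held genes placed on chromosome Y, and 1 of these rows received reads. A single row with so few counts does not settle whether reads could be assigned to the others.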

How the results depend on the processing

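Of the alternative settings in this part, those that matched lists on GC content or removed a GC, length or pseudogene effect were chosen after seeing the data, the pseudogene setting before its own result was seen; the others were fixed before the data were examined. No paired analysis was possible because there was 1 group. Of 255 values that answer a comparison, computed under an alternative that kept both libraries, 208 stayed within the spread between replicates, 1.5 times for counts or the same side of the limits for list ratios, or within the limits set for correlations and the coefficient of variation. Single libraries are tallied apart: shares cannot leave the spread around the mean of 2 libraries, and of 58 percentiles and detected counts 13 moved. In most cases below the cause was not tested.

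Detected members fell under a minimum of 2 TPM to 0 for sort markers and 0 for mast cell and basophil genes. Under 5 TPM they were 0 sort markers, 0 mast cell and basophil, 7 granulocyte-monocyte progenitor, 2 mature neutrophil, 2 dendritic, 4 fibroblast and stromal and 2 endothelial genes. With FPKM, 1 sort marker was detected. Of the other-tissue genes, 1 was detected at 0.5 TPM, 1 with rescaled TPM and 2 with posterior mean TPM. With single libraries, megakaryocyte genes ranged from 7 to 10 and other-tissue genes from 0 to 1.

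Level percentiles with length-matched lists were 94.1 for mature neutrophil, 98.5 for macrophage, 55.2 for mast cell and basophil, 98.2 for B lineage, 84.3 for fibroblast and stromal, 61.0 for endothelial and 19.0 for other-tissue genes. With GC-matched lists they were 57.5 for sort markers, 42.8 for megakaryocyte, 79.6 for granulocyte-monocyte progenitor, 74.6 for mature neutrophil, 96.9 for macrophage, 48.1 for mast cell and basophil, 97.9 for B lineage, 58.0 for endothelial and 4.07 for other-tissue genes. Posterior mean TPM gave 98.8 for macrophage and 23.4 for mast cell and basophil genes, and rescaled TPM 97.9 for B lineage genes. With single libraries they ranged from 49.2 to 77.6 for megakaryocyte, 66.9 to 83.1 for endothelial, 45.4 to 53.6 for sort marker, 10.6 to 13.6 for other-tissue, 97.1 to 99.4 for stem and early progenitor, 96.6 to 98.9 for granulocyte-monocyte progenitor, 76.6 to 81.9 for mature neutrophil, 98.7 to 98.8 for macrophage, 39.1 to 40.3 for mast cell and basophil, 97.8 to 98.0 for B lineage, 87.3 to 91.6 for T and NK, 55.8 to 70.7 for dendritic and 86.1 to 89.0 for fibroblast and stromal genes.

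The coefficient of variation was 0.605 with no filter and 0.520 at 100 or more counts, by construction of which genes enter. The correlation was 0.885 with a pseudocount of 0.1, and 0.957 (Spearman 0.944) with no filter on low values. Genes apart numbered 370.0 higher in replicate 2 and 2703 in replicate 1 with total-count scaling, and 456 and 2844 with TPM ratios. With TPM ratios the median log2 ratio was −1.21 for B lineage and 0.20 for dendritic genes, both then among the random lists, and −0.11 for histone genes, below 0 but above the median of all genes, −0.45. A prior count of 5 gave 0.77 for dendritic genes, no longer apart, and −0.87 for fibroblast and stromal genes, now apart. With lists matched on GC content as well, stem and early progenitor genes (0.47) stood apart and dendritic genes (0.79) did not. Genes under 20 counts over both libraries were too shallow for a ratio.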

Other observations

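Immunoglobulin RNA was abundant beside the B lineage genes. Ighm had 1734 ± 824 TPM and Igkc 893 ± 733 TPM, while the recombination genes Rag1 and Rag2 had 0 TPM in both libraries and the pre-B genes Vpreb1 and Igll1 had 0.0400 ± 0.0566 TPM and 0.235 ± 0.304 TPM. In the myeloid lists, C1qa, C1qb and C1qc exceeded Adgre1 (2.23 ± 2.04 TPM) and Lyz2 (8.25 ± 0.460 TPM) by far. These genes were chosen after their values had been seen.

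Common reference genes differed between the libraries. Actb had 4700 TPM in replicate 1 and 471 in replicate 2, Gapdh 5153 and 371, and Rplp1 37799 and 2130.0, while Rpl18 had 5383 and 17083. Rplp1 has 5 annotated pseudogene copies, and genes with 5 or more but under 20 copies had a median log2 ratio of −0.58. How reads shared with such copies were assigned was not examined for these genes. Gm26917 and Gm42418, annotated as long RNAs, had 36576 ± 23143 TPM and 9104 ± 2095 TPM. They lie next to each other on chromosome 17 (39843013 to 39846341 and 39846958 to 39848788). The origin of their reads, ribosomal RNA included, was not tested, so the values are not taken as expression of long RNAs.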
